A study of Homalium kanaliense and Homalium betulifolium with 6 samples.

How the data were processed

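Leaves of 6 wild plants, 3 of Homalium kanaliense and 3 of Homalium betulifolium, were sequenced. Per the labels' protocols, leaves were kept in RNAlater, total RNA of 1 plant per library was extracted with TRIzol LS and treated with DNase, and polyA libraries were made with a strand-specific Illumina kit. The series' design text gives paired-end sequencing, a de novo assembly per species from the reads of a single plant, and the H. kanaliense transcriptome as the common reference for both species. The deposited values are whole-number read counts per contig, which the authors made on that reference, per the file headers and the contig names. The assembler, the aligner, the counting tool, their settings and the treatment of reads that match several contigs are not given in the sources used here, nor is the plant from which the reference was assembled. Reads from isoforms, alleles or paralogs assembled as separate contigs may therefore be split between them. No file used here gives contig sequences, contig lengths, gene names or coordinates. Of the 52634 contig IDs, 0 could be matched to a gene name, so the 29 gene lists fixed before the data were examined could not be tested, and no length or GC check was possible.

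Library totals ranged from 37057687 to 56616000 reads. Among contigs with 1 to 10 reads, 57.0% to 64.6% of counts were even, depending on the library, against 49.8% to 50.9% above 100 reads. Limits from counts cover counting error only and assume independent reads. Reads of a pair counted separately are not independent molecules, and such limits would then be too low. The limit of a count of 0 was taken as 3 reads per library. No 2 libraries were alike within sampling noise: the smallest reduced chi-square between 2 plants was 110.3, over contigs with at least 20 reads in the pair. Plants are separate individuals per the design text. Whether plants of a species are close relatives is not known here, and the p-values measure the spread between these plants.

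Groups were taken from the sample titles. The test was edgeR 4.0.16 (R 4.3.3) on the counts as deposited: contigs were kept by filterByExpr with its defaults (minimum count 10, minimum total 15), which left 44048 contigs holding at least 99.6% of each library's reads, libraries were scaled by TMM, and glmQLFit with robust estimation and glmQLFTest compared H. kanaliense with H. betulifolium over all 6 plants, without covariates. TMM factors were 1.24, 1.14 and 1.26 in H. kanaliense plants 1 to 3 and 0.546, 0.918 and 1.12 in H. betulifolium plants 1 to 3. Calls are contigs with a Benjamini-Hochberg adjusted p under 0.05. CPM values were computed with edgeR from the TMM-scaled library totals, the SE of a log2 fold change is its size divided by the square root of the quasi-likelihood F, and the biological coefficient of variation is the square root of edgeR's common dispersion fitted within a species. Correlations used log2(CPM + 1) of unscaled library totals, and principal components log2 CPM with a prior count of 2. The test was tested on simulated data with the means, dispersions and library sizes of these 6 plants and 200 changed contigs with at least 100 reads on average: it called 44 of 50 contigs changed 256-fold, 6 unchanged contigs beside the changed ones, and 0 when no contig was changed.

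The rule for named contigs, for files that pair no contig with a gene, was to take the 2 contigs on each side with the largest fold change among those called, with no overlap between species, a mean of at least 10 CPM and at least 10 reads in every plant. Alternatives were median-of-ratios, upper-quartile and library-total scaling, DESeq2 1.42.0, voom of limma 3.58.1, other low-count filters, a stricter threshold of 0.01, glmTreat against a log2 fold change of 1, the replicate number as a block, and each plant left out in turn. A fit without robust estimation, the abundance classes without H. betulifolium plant 3 and the counts of contigs in which a single plant differs were added after the data were seen. Figures were drawn with matplotlib 3.10.9.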

Results

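Leaf transcripts of 2 tree species of the genus Homalium (Salicaceae) from New Caledonia were compared. Homalium kanaliense is given in the labels as a nickel hyperaccumulator, a plant that concentrates this metal in its leaves, and Homalium betulifolium as a species that does not accumulate it. The question of the comparison was which leaf transcripts differ in abundance between the accumulating and the non-accumulating species. Leaves of 3 wild plants of each species, all from serpentine soil, were sequenced as separate libraries. The H. kanaliense leaves were collected on day 11 of month 6 and the H. betulifolium leaves on day 11 of month 9 of the same year. By their coordinates, the H. kanaliense plants stood between 11.7 m and 82.4 m apart, the H. betulifolium plants between 1.85 m and 57.5 m apart, and the species 62.7 km from each other. Species, site, date and the origin of the reference therefore coincided and could not be separated. The 1.85 m between H. betulifolium plants 2 and 3 is a step in the last recorded digit of latitude, so the shortest distances are approximate.

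Reads of all 6 plants were counted on the same 52634 contigs of an H. kanaliense leaf transcriptome. The H. kanaliense libraries held 45034714, 51478909 and 39023490 reads in plants 1 to 3, and the H. betulifolium libraries 56616000, 37057687 and 45487392 reads. All contigs but 1 had reads in H. kanaliense plant 2, while 1630 and 1684 contigs were at 0 in H. kanaliense plants 1 and 3. In H. betulifolium, 8212, 5232 and 3264 contigs were at 0 in plants 1, 2 and 3. Reads were found in every plant of both species for 40257 contigs (76.5%), and 26249 contigs (49.9%) had at least 10 reads in every plant. The contigs are identified by number only, so that no gene name, gene location or function is attached to any contig below, and several contigs may belong to 1 gene.

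As counted on the H. kanaliense reference, the leaf transcriptomes of H. kanaliense plants resembled one another more than those of H. betulifolium plants did. Across contigs, the Pearson correlation of log2(CPM + 1) was 0.943 to 0.953 between the 3 pairs of H. kanaliense plants, 0.851 to 0.915 between the 3 pairs of H. betulifolium plants and 0.836 to 0.897 between the 9 pairs of plants of different species. These correlations are across contigs, which are not independent replicates. The median contig differed by 0.43 to 0.51 (log2, absolute) between H. kanaliense plants and by 0.96 to 1.13 between H. betulifolium plants, against 0.75 to 1.19 between plants of different species. Between 5.57% and 8.34% of tested contigs differed over 4-fold between 2 H. kanaliense plants, and between 22.8% and 26.1% between 2 H. betulifolium plants. The biological coefficient of variation was 0.490 in H. kanaliense and 0.869 in H. betulifolium. From pairs of plants it ranged from 0.463 to 0.539 in the first species and from 0.815 to 0.844 in the second. The pairs share plants and the difference in spread was not tested. H. betulifolium reads were counted on contigs of the other species, with medians of 21, 31 and 54 reads per contig in plants 1 to 3. The medians were 64, 71 and 57 reads in H. kanaliense plants 1 to 3. With at least 10 reads in every plant, the coefficient was 0.375 in H. kanaliense and 0.654 in H. betulifolium. Low counts and sequence differences from the reference can widen the spread, and their share in it was not tested.

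The 3 H. betulifolium plants differed from one another, and on the first principal component plant 3 lay apart from plants 1 and 2. On the first principal component (42.5% of the variance) the H. kanaliense plants had scores of -136.6, -132.6 and -170.1, H. betulifolium plants 1 and 2 had 208.1 and 220.6, and plant 3 had 10.6. On the second component (22.5%) plant 2 had 170.5, against -92.2 and -195.0 for plants 1 and 3. The median contig differed by 1.09 between plants 1 and 2, and plant 2 differed by 0.92 to 0.97 from the H. kanaliense plants. The median contig of plant 3 differed by 0.75 to 0.87 (log2, absolute) from the H. kanaliense plants and by 1.13 and 0.96 from H. betulifolium plants 1 and 2. The Spearman correlation of plant 3 across contigs was 0.813 to 0.833 with the H. kanaliense plants and 0.853 and 0.804 with plants 1 and 2, against 0.851 between plants 1 and 2. Its Pearson correlation was 0.876 to 0.895 with the H. kanaliense plants and 0.886 and 0.851 with plants 1 and 2, against 0.915 between plants 1 and 2. H. betulifolium plants 1 and 2 also concentrated their reads on fewer contigs. The 1000 most counted contigs took 62.8% and 58.6% of their reads, against 47.5% in plant 3 and 44.5%, 47.9% and 44.7% in H. kanaliense plants 1 to 3.

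**Figure D1:**
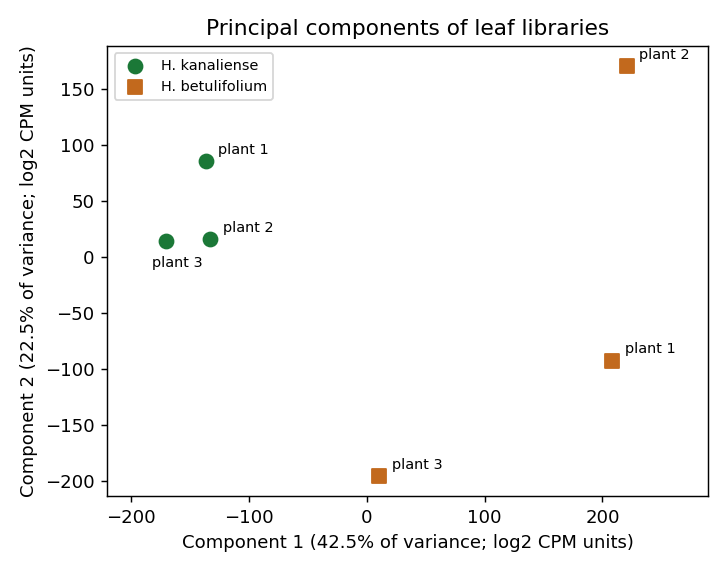
Principal components 1 and 2 of log2 CPM over 44048 tested contigs, with 1 point per plant (circles for H. kanaliense, squares for H. betulifolium). The H. kanaliense plants group at the left, and H. betulifolium plant 3 lies between them and the other 2 plants of its species on component 1.

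Of 44048 contigs tested, 390 differed in abundance between the species (0.885%), of which 282 (72.3%) were higher and 108 (27.7%) lower in H. kanaliense. All 390 differed at least 2-fold, and in all of them the 3 plants of one species lay above the 3 plants of the other. The contigs higher in H. kanaliense were low or unread in H. betulifolium, with a median of 5.89 CPM in H. kanaliense and 0.022 CPM in H. betulifolium. The contigs lower in H. kanaliense had reads in every H. betulifolium plant, with a median of 70.9 CPM there and 4.22 CPM in H. kanaliense. The test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05; 6074 contigs had an unadjusted p under that value. The lowest adjusted p of any contig was 0.025, and no call remained without any 1 of H. kanaliense plants 1, 2 or 3 or H. betulifolium plants 1 or 2 (4113 to 7605 contigs at an unadjusted p under 0.05). Leaving out H. betulifolium plant 3 gave 700 calls, 353 higher and 347 lower, 302 of them among the 390. DESeq2 called 3280 contigs (2031 higher and 1249 lower) and limma-voom 775 (578 higher and 197 lower), including all 390 and 381 of the 390.

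The differences among called contigs were large. Contigs lower in H. kanaliense had a median log2 fold change of -4.26, a 19.2-fold difference. Contigs higher in H. kanaliense had a fitted median of 7.88, but 82 of the 282 were at 0 in all H. betulifolium plants, where a fitted value depends on the prior count. With those 82 set to the bound that 3 reads per H. betulifolium library allow, the median was 5.91. Called-higher contigs with some reads, but fewer than 3 per library, kept their fitted values, so 5.91 is not a lower bound of the median. In the 50 called-higher contigs with at least 10 reads in every plant the median log2 fold change was 3.90, and it was -4.13 in the called-lower contigs of that kind, all but 7 of the 108. The smallest called differences were 4.27-fold for the higher and 3.79-fold for the lower contigs. In counts simulated from these libraries over 44048 contigs, the test called 0 of 50 contigs changed 4-fold, 33 of 50 changed 16-fold and 46 of 50 changed 64-fold. The changed contigs averaged at least 100 reads, whereas 232 of the 282 called-higher contigs had under 10 reads in at least 1 H. betulifolium plant. Test and simulation both gave the 2 species 1 shared spread per contig, although the spread was larger in H. betulifolium.

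Called contigs higher and lower in H. kanaliense were found at different abundances. Among 15867 contigs with a mean under 1 CPM over the 6 plants, 37 were higher and 0 lower in H. kanaliense. Among 15055 contigs between 1 and 10 CPM, 185 were higher and 22 lower, and among 11394 contigs between 10 and 100 CPM, 58 were higher and 49 lower. Among 1732 contigs at 100 CPM or more, 2 were higher and 37 lower. The median log2 fold change over all tested contigs was 0.0044, and by class it was 0.39, 0.01, -0.27 and -0.63 in the same order. Of the 1000 contigs with the highest mean CPM, 26 were called, all lower in H. kanaliense under TMM scaling. Without H. betulifolium plant 3, the class at 100 CPM or more held 5 higher and 110 lower contigs, the class from 10 to 100 CPM 97 and 180, the class from 1 to 10 CPM 234 and 57, and the class under 1 CPM 17 and 0. In that fit 81 of the 1000 most abundant contigs were called, 4 higher and 77 lower. The species shared 57 of the 100 contigs with the highest mean CPM in each. The reference can shape this pattern: all contigs but 1 had reads in H. kanaliense plant 2, whereas a called-higher contig could be at 0 in every H. betulifolium plant. H. betulifolium plants 1 and 2 also concentrated their reads on fewer contigs, as given above. How much of the pattern by abundance comes from either was not tested.

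**Figure D2:**
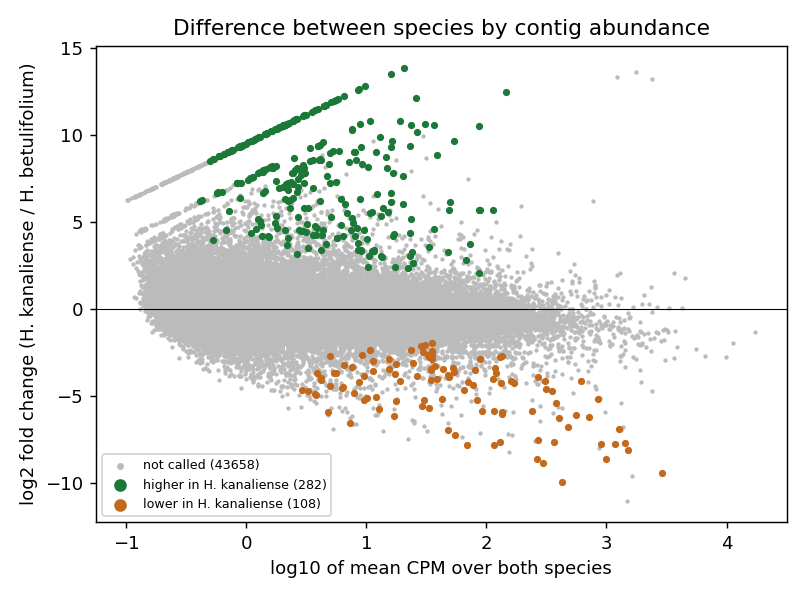
Log2 fold change (H. kanaliense over H. betulifolium) against log10 of the mean CPM of both species for 44048 tested contigs, with 282 called-higher and 108 called-lower contigs in colour. The straight upper edge holds contigs with no reads in H. betulifolium, whose fitted values depend on the prior count.

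**Figure D3:**
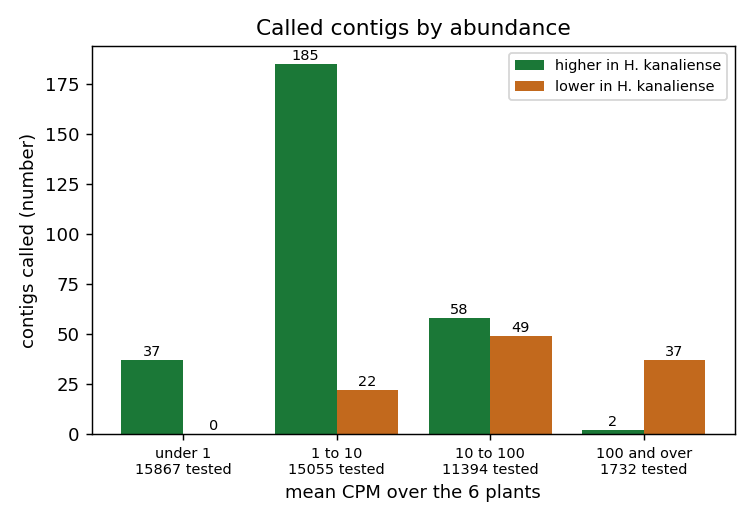
Number of contigs called higher or lower in H. kanaliense in 4 classes of mean CPM over the 6 plants. Called-higher contigs are most numerous between 1 and 10 CPM (185), and 37 of the 39 calls at 100 CPM or more are lower in H. kanaliense.

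The values of every plant were set apart by species in more contigs than the test called. In 10485 of the tested contigs (23.8%) the 3 plants of one species lay above the 3 plants of the other, where chance gives 10% for 3 against 3. The 10485 contigs were 6453 with H. kanaliense above and 4032 with H. betulifolium above. The share of 10% holds for plants that are exchangeable. Here the reference came from H. kanaliense, which can favour that species, and site and date differed with species. The excess over 10% can therefore not be assigned to species alone.

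The most changed contigs read in every plant were taken as examples, 2 on each side, with IDs that name no gene. Hkan_v1_contig_1053 was higher in H. kanaliense, at 97.8 ± 39.3 CPM (SD, n = 3) against 1.34 ± 1.44 CPM in H. betulifolium. Its log2 fold change was 6.17 ± 0.97 (SE), and its adjusted p from edgeR's quasi-likelihood test was 0.045. Hkan_v1_contig_10003 was at 31.8 ± 14.4 CPM in H. kanaliense and 0.447 ± 0.056 CPM in H. betulifolium, a log2 fold change of 6.15 ± 0.52 (SE) with an edgeR adjusted p of 0.025. In H. betulifolium these contigs rested on 10 to 152 and on 12 to 23 reads per plant. Hkan_v1_contig_11114 was lower in H. kanaliense, at 8.41 ± 1.47 CPM against 5745 ± 4608 CPM in H. betulifolium, with a log2 fold change of -9.42 ± 1.18 (SE) and an edgeR adjusted p of 0.033. Its H. betulifolium values were 4805, 10751 and 1679 CPM in plants 1, 2 and 3, from 148554, 365272 and 85578 reads. Hkan_v1_contig_26202 was at 0.872 ± 0.470 CPM in H. kanaliense and 848 ± 672 CPM in H. betulifolium, a log2 fold change of -9.92 ± 1.10 (SE) with an edgeR adjusted p of 0.027. In 33 contigs on the higher side and 85 on the lower side the same conditions for being named were met. Like the other calls, these 4 lost significance without any 1 plant other than H. betulifolium plant 3. Their direction was unchanged, which their choice without overlap nearly fixed. Over 16 alternative fits the log2 fold change was 5.70 to 7.48 for Hkan_v1_contig_1053 and 5.71 to 6.64 for Hkan_v1_contig_10003. It was -9.93 to -8.61 for Hkan_v1_contig_11114 and -10.4 to -9.09 for Hkan_v1_contig_26202. At an adjusted p of 0.01 edgeR called 0 contigs, and in edgeR's glmTreat test against a log2 fold change of 1 Hkan_v1_contig_1053 had an adjusted p of 0.058.

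**Figure D4:**
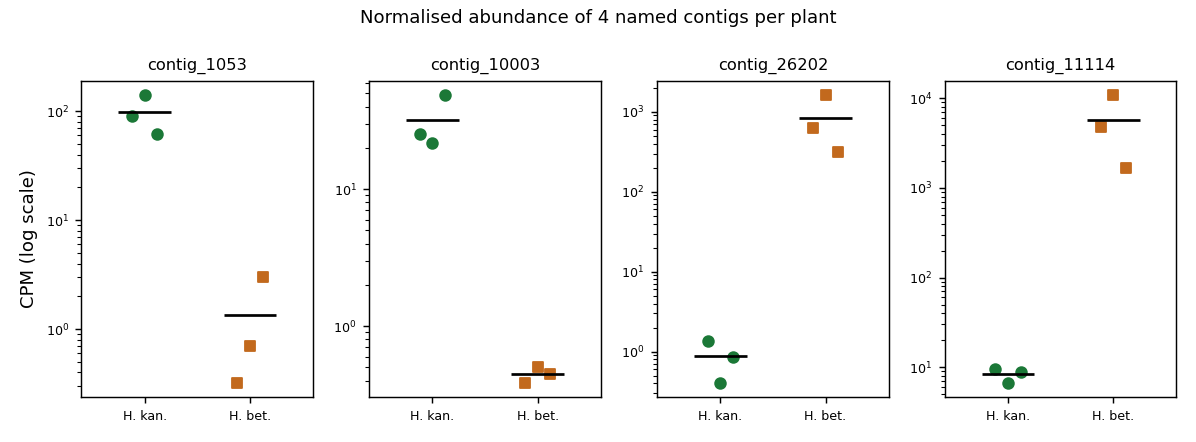
CPM per plant on a log scale for the 4 named contigs (circles for H. kanaliense, squares for H. betulifolium, bars for the mean of 3 plants). In each contig all plants of one species lie above all plants of the other.

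A further group of contigs had reads in one species only. With at least 10 reads in each H. kanaliense plant and 0 in each H. betulifolium plant, 269 contigs were found, and the reverse condition was met by 0 contigs. The reference was built from H. kanaliense, so a transcript of H. betulifolium alone has no contig on which to be counted. All contigs but 1 had reads in H. kanaliense plant 2, so the reverse count could not exceed 1 and says nothing about the species. The 269 contigs were mostly of low abundance, with a median of 0.883 CPM in H. kanaliense and a highest value of 40.9 CPM, and 48 of them had at least 100 reads in every H. kanaliense plant. Against 3 reads per H. betulifolium library, the limit that a count of 0 allows for independent reads, the median contig of this group was at least 10.8-fold higher in H. kanaliense, and the most abundant at least 503-fold. If both reads of a pair were counted, the limit is higher and these folds are lower. The limit of 3 reads equals 0.097, 0.088 and 0.059 CPM in H. betulifolium plants 1, 2 and 3 and covers counting error of independent reads only. Of the 269 contigs, 257 entered the test and 82 were called. The count depended on single plants, with 684 contigs without H. betulifolium plant 3, 429 without plant 1, 469 without plant 2, and 429 and 410 without H. kanaliense plants 1 and 3. Without H. kanaliense plant 2, the reverse condition was met by 60 contigs. Reads on these contigs can be missing because the transcript was not made or because its sequence differs from the reference, and the counts do not separate the 2 cases.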

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

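The fit without robust estimation and the stricter tests of the named contigs were chosen after the data were seen. The direction of all 390 calls was kept under every alternative fit in which they were tested, but their number was not. The species did not overlap in any of the 390, so a change of direction was hardly possible and its absence decides little. Counts of all calls, of higher and of lower contigs stayed within 1.5 times under median-of-ratios (376) and upper-quartile scaling (387), without a low-count filter (366), with at least 1 CPM in 3 plants (525) and without robust estimation (403). Library totals alone gave 452 higher contigs (80.7% of calls) and moved the median log2 fold change to 0.48. With at least 10 reads in every plant, a filter that removes contigs unread in one species, 179 contigs differed (all at least 2-fold), 79 higher and 100 lower. DESeq2 gave 3280 (2031 higher, 1249 lower, all at least 2-fold) and limma-voom 775 (578 and 197, all at least 2-fold; median log2 0.198). The threshold of 0.01 left 0, and glmTreat 153 (110 and 43). Leaving out 1 plant gave 0 to 700 calls, all at least 2-fold (0 to 353 higher and 0 to 347 lower). The 5 fits with 0 calls by edgeR had 4113 to 7605 contigs at an unadjusted p under 0.05 and a lowest adjusted p of 0.057 to 0.121; other tools were not run on 5 plants. With the replicate block edgeR called 0 contigs, with 4722 at an unadjusted p under 0.05, a lowest adjusted p of 0.117 and a median log2 fold change of 0.198. The same replicate numbers stand for different plants, sites and dates, deviations from the species means correlated at -0.0013, -0.073 and 0.152 for plants 1, 2 and 3, and not every plant correlated best with its own number. Each of the 4 named contigs was called in 10 of 16 alternative fits. Each kept its direction in all 16, which the choice of contigs without overlap nearly fixed. The 16 fits do not include the threshold of 0.01, which 0 of the 4 passed, or glmTreat, which 3 of the 4 passed (adjusted p 0.030 to 0.058). The 269 contigs read in H. kanaliense alone became 684 with a minimum of 1 read, 93 with 50 reads, 590 with up to 2 reads allowed in the other species, 265 after thinning, and 276 to 684 with 1 plant left out. The reverse count stayed at 0 except without H. kanaliense plant 2 (0 to 60 with 1 plant left out), the plant with reads on all contigs but 1. The coefficient of variation in H. betulifolium was 0.947 with library totals, 0.886 with upper quartiles, 0.891 without a filter, 0.809 with at least 1 CPM and 0.654 with 10 reads in every plant; in H. kanaliense it was 0.539 without a filter and 0.375 with 10 reads in every plant. It was the larger in H. betulifolium under each of these settings. Where not stated, the cause was not tested. The gene list tests and the division by contig length were not run, since the files pair contigs with neither names nor lengths.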

Other observations

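The counts over splits and the tests of scaling, of RNA mixed into a library, of a mislabelled plant judged on expression and of equal carryover fractions were chosen only after the result was seen. The IDs named in this part were chosen after their values were seen.

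Contigs missing from single plants were common. Read at 10 or more in every plant but 1, 556 contigs were at 0 in H. betulifolium plant 1, 337 in plant 2 and 82 in plant 3, and at most 142 were at 0 in H. kanaliense plants 1 and 3 each. In H. kanaliense plant 2 this number was 0, and 132 contigs with at least 10 reads there had no read in any other plant, where each of the other 5 plants had 0 such contigs. A further 59 contigs were read in H. kanaliense plant 2 and in every H. betulifolium plant but not in H. kanaliense plants 1 and 3, with a median of 86 reads in plant 2. Conversely, 60, 72 and 237 contigs were read in every H. kanaliense plant and in a single H. betulifolium plant, numbered 1, 2 and 3. After thinning all libraries to 37057687 reads, H. kanaliense plant 2 had 3 contigs at 0, against 1705 to 9325 in the other plants. These counts are what a reference assembled from the reads of H. kanaliense plant 2 gives, although no label names that plant.

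The split of the plants by species gave the only calls. Of the 10 splits of the 6 plants into 3 and 3, 1, the real one, gave 390 calls, with 282 higher and 108 lower and all 390 at least 2-fold, and the highest other split gave 0. With 10 splits no share under 0.05 can be reached. Every other split also puts plants of both species in each group, which turns a difference between the species into spread within groups. The 0 calls there therefore say little about chance. The split with H. kanaliense plant 1 beside H. betulifolium plants 1 and 2 had the most contigs at an unadjusted p under 0.05 among the others, 2900 against 6074 in the real split.

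More contigs were called higher than lower in H. kanaliense (282 against 108), while without H. betulifolium plant 3 both numbers rose, to 353 and 347. The choice among the 4 scalings tried was not the reason, since the lowest share of higher calls over them was 71.3%. Scaling as such stays open. TMM, median-of-ratios and upper-quartile scaling centred the contigs alike, at median log2 fold changes of 0.0044, -0.050 and 0.027. Library totals moved that median to 0.48, toward more higher calls, and no scaling with a shift the other way was tried. Whether a reference assembled from H. kanaliense plant 2 made the excess of higher calls stays open. That plant was the highest of its species in 24.1% of the called-higher contigs, below the bound of 40% set beforehand, and in 29.3% of all tested contigs. The median log2 difference of the called-higher contigs (0.1 CPM added) was 4.96 with plant 2 and 4.99 without it. A call needs the 3 plants to be alike, however, and the called-lower contigs gave 25%, so values from called contigs cannot decide it. A reference that holds H. kanaliense sequences only stays open as well: the share of 38.4% higher among calls with a mean of at least 10 reads per plant in each species decides nothing, because that minimum removes contigs for being low in H. betulifolium. A difference between the species themselves stays open too and was not tested.

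H. betulifolium plant 3 differed at least 8-fold from both other plants of its species, which agreed within 2-fold, in 347 contigs of at least 10 CPM in 1 of these plants, against 111 and 221 for plants 1 and 2 and 46 to 94 for the H. kanaliense plants. Over 139 contigs low in plants 1 and 2, the level of plant 3 relative to H. kanaliense had an interquartile range of 6.14 on the log2 scale. Of these contigs, 30 were at or above the H. kanaliense mean and 79 at a sixteenth of it or less. Mixed-in RNA like that of the 3 sampled H. kanaliense plants, as the only source of these reads, gives 1 fraction and is argued against. A mixture beside expression by plant 3 itself, a small mixture, or RNA from a plant of another stand was not tested and stays open. A mislabelled plant like the 3 sampled H. kanaliense plants is argued against by a lowest median difference of 0.749 from them, against at most 0.513 among them. By this measure plant 3 still lay nearer to them (up to 0.868) than to plants 1 and 2 (1.13 and 0.962). Plant 2 also lay nearer to the H. kanaliense plants than to plant 1 (0.924 to 0.971 against 1.09). Spearman correlation put plant 3 nearest to H. betulifolium plant 1 (0.853). Pearson correlation put it nearest to H. kanaliense plants 2 and 3 (0.895 each), against 0.886 with H. betulifolium plant 1. An H. kanaliense plant of another stand stays open, since no such plant was compared: of 684 contigs read in every H. kanaliense plant and at 0 in plants 1 and 2, 39.3% were also at 0 in plant 3, short of the bound of over 40% set beforehand, and 0% to 10.7% in left-out H. kanaliense plants. Unequal library depth stays open. At equal depth after thinning, plant 3 stood apart in 349 contigs (347 before), against 107 and 222 for plants 1 and 2. The ratio of plant 3 to the mean of plants 1 and 2 was then 2.12 (95% counting interval 1.82 to 2.47). That interval includes the bound of 2, so the test does not decide. The bound was set for a count that was itself added after the data were seen. Concentration of reads cannot be told apart from a difference between the plants, because thinning left it unchanged. The 1000 most counted contigs then took 62.8%, 58.6% and 47.5% of the reads in plants 1, 2 and 3. A biological difference between these plants was not tested.

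In H. kanaliense plant 2, the contigs Hkan_v1_contig_40, Hkan_v1_contig_60 and Hkan_v1_contig_346 held 845697, 614762 and 425770 reads, together 3.66% of the library, while H. kanaliense plant 1 had 0 reads on each and H. betulifolium plants 1 and 3 had 1 read in all. H. kanaliense plant 3 had 411 reads on them and H. betulifolium plant 2 had 102. Carryover from the plant 2 library is a candidate explanation of these traces, since the fraction of the plant 2 reads differed by 1.22 times between the 3 contigs in H. kanaliense plant 3 and by 1.37 times in H. betulifolium plant 2. Of 30 contigs with at least 20 reads expected from such carryover, 0 held under 0.5 of it in H. kanaliense plant 3, which decides nothing because contigs abundant in plant 2 are read in plant 3 anyway. A low level of the same RNA in both plants predicts equal fractions too and stays open, and what the contigs encode is not known here.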
